A study of Caenorhabditis elegans with 6 samples.

How the data were processed

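Total RNA from dissected intestines of Caenorhabditis elegans L4 larvae was profiled on 6 arrays, 3 of wild-type N2 and 3 of strain BJ142 with the allele ifo-1(kc2). Per the labels' protocols, worms grew on OP50 bacteria, intestines were extruded through an incision in animals held in levamisole, and 40 (N2) or 80 (mutant) of them were pooled for each RNA isolate, with DNase treatment on the column. Biotinylated cDNA came from 20 ng of total RNA after whole-transcriptome amplification (Nugen Ovation Pico WTA V2 with the Encore Biotin module), per the labels. Amplification from such small inputs can widen the spread between arrays, and pool size cannot be separated from strain. The 3 arrays of a strain are independent RNA isolates, per the labels.

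The deposited table holds log2 signal values, 1 line per probe set of an Affymetrix gene array and 1 column per array. Per the submitters' processing notes the authors used Affymetrix Expression Console, RMA and Transcriptome Analysis Console; versions and the role of each are not given in the sources used here. RMA corrects background, quantile-normalizes probes between arrays and summarises them into log2 values, which compresses differences of dim probe sets. The column ranges fit a log2 scale (0.878 to 14.05 over all arrays), and quartiles of the arrays lay close together except in ifo-1(kc2) replicate 1, whose lower quartile was 3.40 against 2.98 to 3.10 in the others. Quantile normalization of 6 arrays together leaves little such difference. Whether all 6 were normalized together is not given in the sources used here, and every difference that involves that array carries this doubt. The genome build of the array design is not given in the sources used here, so no coordinates are printed. No detection calls were used here, and low signals have no stated background limit.

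Of 28387 probe sets, 25546 had 1 gene symbol in the platform annotation, 646 had several and 2195 had no listed gene. Symbols were updated through Entrez identifiers against an annotation table of assembly WBcel235 (25447 genes matched, 40 symbols changed). That table also gave which genes neighbour each other. The 37 genes with more than 1 probe set were represented by the one with the highest mean, which left 25498 genes, 18812 of them protein-coding. Probe sets with several or no genes entered only a fit of all probe sets, and no gene is named from them.

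The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, no covariate, all 6 arrays). Genes with a Benjamini-Hochberg adjusted p under 0.05 over all 25498 genes are called changed, and folds are ratios of geometric means. Before the data were examined, 37 gene lists and 10 lists of tissue markers were fixed, together with the model, the threshold, the alternatives and the rule for the genes named. The rule takes ifo-1 and all measured intestinal intermediate filament genes; the 15 largest rises and the 15 largest falls among changed genes whose arrays do not overlap and whose signal in the higher strain is above the median of all genes; and, for each list, up to 4 members with the smallest adjusted p, or 2 with the largest differences where none passed. Genes named beyond the rule are said to be so. Lists with at least 5 measured genes were tested with camera (preset correlation 0.01, adjusted over 47 lists), again with an estimated correlation, and with fry. Their members were also adjusted over the list alone. Some members of the lists had no probe set of their own, among them hsp-16.1, hsp-16.11, hsp-16.48 and hsp-16.49.

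Data were simulated with the real means and the moderated variances of the fit for 25498 genes. There were 5 simulations of 3 arrays against 3, with 200 genes changed in each. Noise was independent between genes and alike in all arrays, whereas estimated array weights ran from 0.32 (ifo-1(kc2) replicate 1) to 1.94 (N2 replicate 2). The fit recovered 15.2% of genes changed by 1 on the log2 scale, 92.8% of those changed by 2 and 99.1% of those changed by 3. Of its calls, 6.64% were false. In this simpler setting, changes near 2-fold were mostly missed at this number of arrays. No pair of arrays held identical values.

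Alternatives were a second quantile normalization, centring of arrays, 2 filters on dim genes, an intensity trend, robust and unmoderated variances, an unadjusted threshold with a 2-fold change, array weights, the mean of probe sets, every probe set on its own, the replicate number as a block, each array left out in turn, and other tests for lists. A fit of protein-coding genes only, and the counts of list members without ifo-1(kc2) replicate 1, were chosen after seeing the data.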

Results

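The series measured gene expression in the intestine of the nematode Caenorhabditis elegans in 2 strains. N2 is the standard wild-type strain. The second strain, BJ142, carries the mutant allele ifo-1(kc2); ifo-1 encodes an organiser of the intermediate filament network under the apical membrane of intestinal cells. The title of the series names the question as how this network responds to and protects from microbes and toxins. Intestines were dissected from larvae at the L4 stage, without pharynx and tail, and pooled: 40 intestines per N2 pool and 80 per pool of the smaller mutants, so pool size and strain went together. Each strain had 3 pools from independent RNA isolates, and cDNA amplified from 20 ng of RNA of each was hybridised to 1 array. The 6 arrays gave log2 signals for 25498 genes, with array medians of 4.41, 4.41 and 4.44 over all probe sets for N2 and 4.81, 4.46 and 4.54 for ifo-1(kc2) replicates 1, 2 and 3. Correlations over genes ranged from 0.977 to 0.984 between N2 arrays, from 0.968 to 0.978 between mutant arrays and from 0.952 to 0.965 between strains. The first principal component held 43.6% of the variance and separated the strains. The second held 22.1% and set ifo-1(kc2) replicate 1, the array with the highest median, apart from the other mutant arrays. The number of arrays limits the precision of every value below.

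The mutated gene itself was lower in the mutant. The ifo-1 signal was 10.81 ± 0.14 (SD, n = 3) in N2 and 8.79 ± 0.45 (SD, n = 3) in ifo-1(kc2), a log2 change of -2.01 with a standard error of 0.26, or 4.04-fold, at a limma adjusted p of 0.0112. All 3 mutant arrays lay below all 3 N2 arrays; an exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. Without N2 replicate 3 the adjusted p rose to 0.0548. Where the probes lie relative to the kc2 lesion is not given in the sources used here, so this value checks the strain labels only as far as the probes read the altered transcript. Of the 6 genes for intestinal intermediate filament proteins, 1 rose: ifd-2 went from 10.20 ± 0.07 to 11.61 ± 0.11 (SD, n = 3), 2.66-fold, at an adjusted p of 0.00953. The log2 change was 1.41, and its call was lost without N2 replicate 3 (adjusted p = 0.052). The log2 differences of the other 5 did not pass the test: 0.10 for ifb-2, 0.22 for ifc-1, 0.13 for ifc-2, 0.37 for ifd-1 and -0.18 for ifp-1. With 1 array left out they ranged from -0.02 to 0.22, 0.08 to 0.34, 0.07 to 0.19, 0.21 to 0.65 and -0.46 to 0.01. Adjusted over the list alone, 1 gene passed as well. The list as a whole did not stand apart from other genes (median log2 change 0.17, which turned to -0.03 when arrays were centred; camera adjusted p = 0.173), although without ifo-1(kc2) replicate 1 it reached an adjusted p of 0.0467. Without N2 replicate 3 the median was 0.08.

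**Figure D1:**
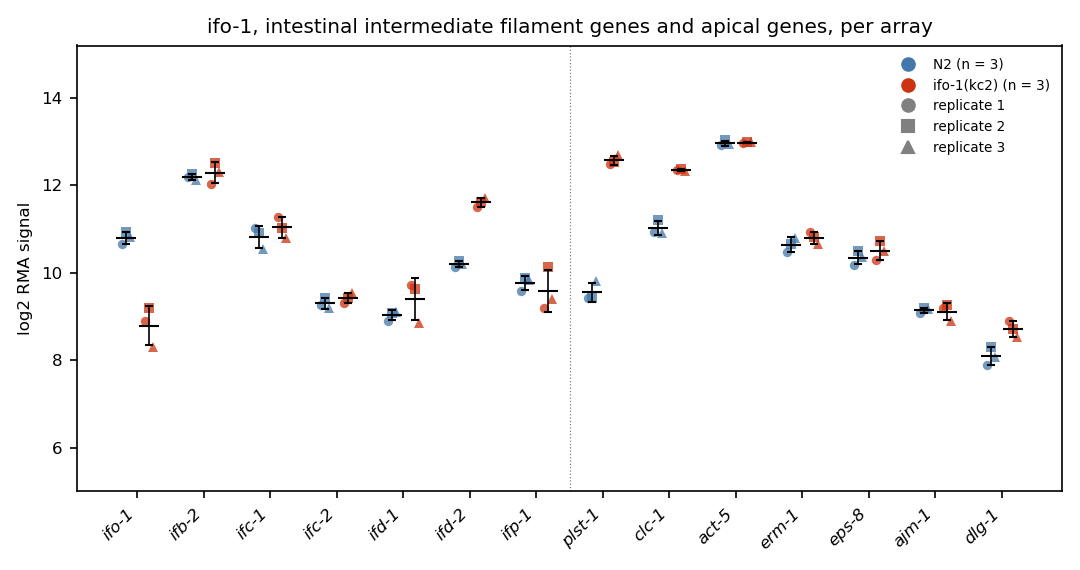
Log2 array signal (vertical axis) of ifo-1, the 6 intestinal intermediate filament genes and, right of the dotted line, genes of the apical surface and junctions; points are single arrays, shapes are replicates, horizontal bars are means and error bars are SD (n = 3 per strain). The points show ifo-1 lower in ifo-1(kc2), and ifd-2, plst-1 and clc-1 higher.

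Of 25498 genes tested with limma, 552 changed at a Benjamini-Hochberg adjusted p under 0.05: 424 were higher in ifo-1(kc2) and 128 were lower. Of these, 535 changed at least 2-fold (411 higher and 124 lower), and 65 rose and 9 fell at least 8-fold. For all 552, the 3 values of one strain lay beyond those of the other; among all genes tested 20.4% did, where chance gives 10%. The share of higher genes among the changed genes was 76.8%. It was 64.8% after a second quantile normalization (368 higher, 200 lower) and 54.4% after each array was centred on its median (297 higher, 249 lower), because these scalings moved the median log2 change of all genes from 0.05 to -0.05 and -0.15. The number of changed genes was 245, 228 and 161 without N2 replicate 1, 2 and 3, and 239 without ifo-1(kc2) replicate 2. In each of the 6 fits with 1 array left out, 127 of the 552 genes passed the threshold, 23 of them lower.

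The largest rises included genes of detoxification, cell contacts and innate immunity. The UDP-glucuronosyltransferase gene ugt-18 rose 51.9-fold, from 4.01 ± 0.81 to 9.71 ± 0.22 (SD, n = 3, adjusted p = 0.000953). The claudin-like gene clc-11 rose 47.1-fold, from 5.36 to 10.92. The pals genes pals-39, pals-37 and pals-14 rose by log2 values of 5.28, 4.96 and 4.68, and the infection response gene irg-5 by 4.92, to a signal of 11.66 ± 0.50 (SD, n = 3). The C-type lectin genes clec-60 and clec-174 rose by 5.23 and 4.90, and the lysozyme gene lys-9 by 4.41. The remaining 6 of the 15 largest rises were genes with sequence names: Y26D4A.3 (39.3-fold), H02F09.3 (log2 change 5.26), F42C5.3 (5.23), Y47H9C.1 (4.78), F15B9.6 (4.63) and R07C12.1 (4.61). N2 signals of these 15 genes lay between 2.77 for Y26D4A.3 and 6.74 for irg-5. Signal over background was not measured, so folds and ranks of rises from low signals depend on the low end of the arrays. Of the falls, cTel55X.1 was the largest, from 11.04 ± 0.03 to 3.66 ± 0.75 (SD, n = 3), a log2 change of -7.37. The ceramide glucosyltransferase gene cgt-2 fell by 5.34 on the log2 scale, from 8.12 to 2.78, and pud-3 and pud-4 by 5.33 and 5.27. The stearoyl-CoA desaturase gene fat-7 fell 17.1-fold, from 10.30 ± 0.80 to 6.21 ± 0.94 (SD, n = 3, adjusted p = 0.0124). The non-coding genes ZK836.11, ZK836.5, ZK836.17 and ZK836.15 had log2 changes of -3.79, -3.53, -3.31 and -2.92. Others among the 15 largest falls were the short-chain dehydrogenase gene dhs-26 (-3.64), pho-8 (-2.92), the carboxylesterase gene cest-28 (-2.92), Y51A2D.18 (-2.90), oac-32 (-2.87) and the cuticlin-like gene cutl-18 (-2.83). Of these 30 genes, 21 passed in each of the 6 fits with 1 array left out. Of the 30, 26, 23 and 22 passed without N2 replicate 1, 2 and 3, and 26, 24 and 27 without ifo-1(kc2) replicate 1, 2 and 3; pals-14, lys-9, pud-3, pud-4, fat-7, dhs-26, pho-8, ZK836.15 and oac-32 were each lost at least once (adjusted p up to 0.129).

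**Figure D2:**
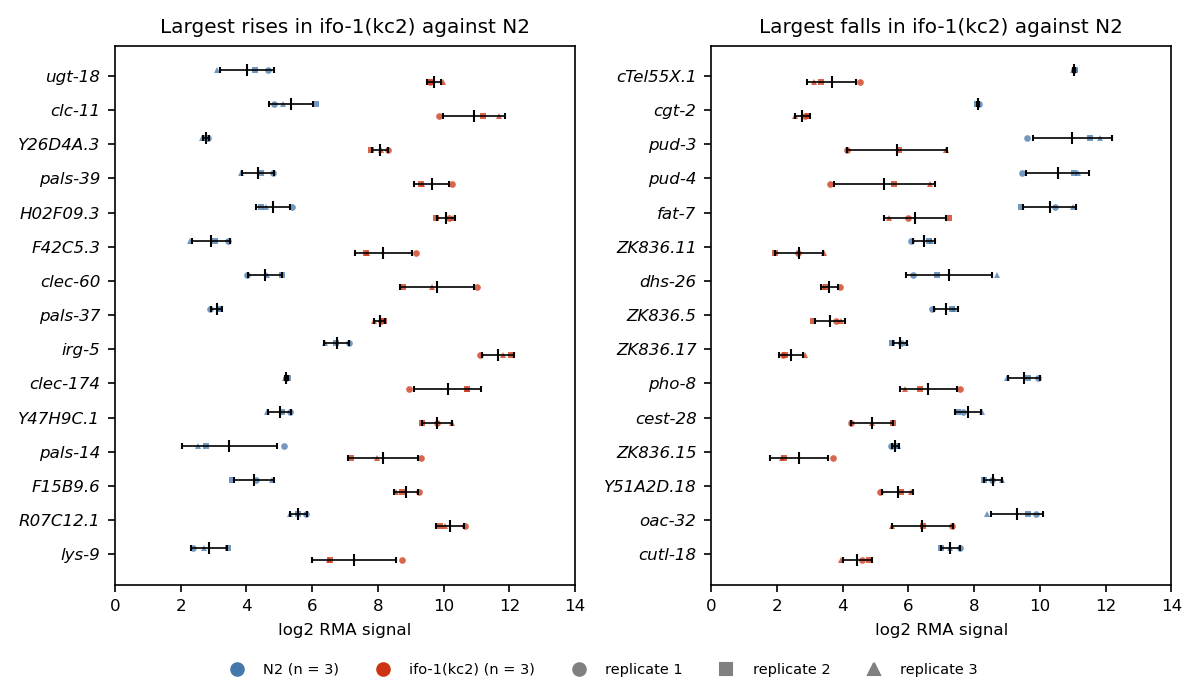
Log2 array signal (horizontal axis) of the 15 largest rises and the 15 largest falls; points are single arrays, shapes are replicates, vertical ticks are means and error bars are SD (n = 3 per strain). In each gene the 3 arrays of one strain lie apart from the 3 of the other; cTel55X.1 and cgt-2 drop from 11.04 and 8.12 to 3.66 and 2.78.

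By median over all 6 arrays the 2 largest list shifts were in immune response genes. Without ifo-1(kc2) replicate 1, hypodermis and cuticle markers (1.05) exceeded both, and without N2 replicate 3 or ifo-1(kc2) replicate 3 (0.96 and 1.21) they exceeded the second. The list named for the intracellular pathogen response, which microsporidia and viruses induce, had 8 of 37 measured genes higher and none lower. All 37 had a positive difference (18 passed when adjusted over the list alone). Induction of its members by infection was not tested here, and the N2 median level of the list was 3.71. Its named genes were pals-39, pals-37, pals-32 (17.1-fold higher) and the Skp1-related gene skr-5 (log2 change 2.35, SE 0.24), each past the threshold in all 6 fits with 1 array left out. The median shift of the list was 1.63 (camera adjusted p = 5.5e-16, but adjusted p = 0.433 with an estimated correlation). By array it was 3.13 in ifo-1(kc2) replicate 1, the array with the higher median signal, against 0.83 and 0.87 in replicates 2 and 3. Without replicate 1 the median was 0.77 with 9 genes higher; without N2 replicate 2 or 3, 5 and 4 genes were higher. The list of immune effectors named for the p38 kinase PMK-1 had 7 higher and 1 lower of 23 (14 and 2 adjusted over the list alone). Dependence of its members on PMK-1 was not tested here. The median shift of this list was 1.02, with array medians of 0.86, 0.95 and 1.02 in the mutant (camera adjusted p = 1.3e-06, but adjusted p = 0.29 with an estimated correlation). Here clec-60, irg-5 and K08D8.4 (2.37, SE 0.22) rose and F55G11.2 fell (-1.63, SE 0.19); 4 and 3 genes were higher without N2 replicate 2 and 3, and 4 without ifo-1(kc2) replicate 3.

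Other immune families changed in part. Among 247 C-type lectin genes, 14 rose and 2 fell (30 and 9 adjusted over the list alone); clec-42, clec-86, clec-140 and clec-82 rose by 3.25, 3.44, 3.40 and 3.43. The median shift of this family was 0.19 and turned to -0.01 when arrays were centred, while the camera call was made in both (adjusted p = 0.0253 and 0.00906; 0.704 with an estimated correlation) and was lost without N2 replicate 1 and ifo-1(kc2) replicate 3. Without ifo-1(kc2) replicate 1 the median was 0.02. Without N2 replicate 1 and 3, 9 and 7 genes of the family were higher. Of 97 lysozyme, saposin and antimicrobial peptide genes, 9 rose and 1 fell (17 and 5 adjusted over the list alone), with spp-21 up by 3.04, nlp-31 by 2.31 and lys-9 by 4.41. The invertebrate lysozyme gene ilys-5 fell from 13.41 ± 0.12 to 10.59 ± 0.24 (SD, n = 3), 7.07-fold. Without N2 replicates 1, 2 and 3, 5, 4 and 4 of this list were higher, and without ifo-1(kc2) replicates 1, 2 and 3, 6, 3 and 5. Without ifo-1(kc2) replicate 1, 3 genes of the list were lower, against 1 in each other such fit. The 10 genes with lys symbols had a median log2 change of -0.45, although 2 of them rose. The list's shift of 0.21 missed the threshold (camera adjusted p = 0.0622) and passed it under both other scalings (0.00904 and 0.0106). There the genes past the threshold were 8 higher and 3 lower after the second quantile normalization, and 6 higher and 6 lower with arrays centred, where the median was 0.00. Of 25 genes of p38 and other MAPK stress signalling, 1 rose, mpk-2 (2.82-fold), with 7 adjusted over the list alone; the median shift was 0.23 (camera adjusted p = 0.00257, but adjusted p = 0.443 with an estimated correlation). With arrays centred the median was 0.02 and no gene passed. The mpk-2 call was also lost without N2 replicates 1 and 3 and ifo-1(kc2) replicates 2 and 3 (adjusted p up to 0.126). No gene among 28 chitinase-like genes passed; the largest differences were 0.88 for chil-13 and 0.63 for chil-18, and the list did not shift (adjusted p = 0.672).

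Genes of fat and one-carbon metabolism lay lower. Of 45 genes of fatty acid and lipid metabolism, 4 fell and none rose, over all genes and adjusted over the list alone: fat-7, the desaturase gene fat-5 (-2.19, SE 0.39), the diacylglycerol acyltransferase gene dgat-2 (2.29-fold lower) and lbp-8, for a lysosomal lipid carrier (-1.73, SE 0.31). The median shift was -0.25 (camera adjusted p = 0.000104, but adjusted p = 0.29 with an estimated correlation). With 1 array left out this median ranged from -0.32 to -0.17. Without N2 replicates 1, 2 and 3, 1, 2 and 0 of the 4 passed (none in the last case, where fat-7 had an adjusted p of 0.0519), and 1 without each mutant array. With arrays centred 6 genes of the list were lower. One-carbon cycle and propionate genes had no member past the threshold in 28 (5 lower adjusted over the list alone, 4 with arrays centred, 1 after a second quantile normalization and 3 among genes above the median level), with differences of -1.62 for nhr-114 (adjusted p = 0.0586) and -1.42 for the methionine synthase gene metr-1 (0.0834). The median of this list was -0.51, with 24 of the 28 below 0 (camera adjusted p = 2.2e-07, but adjusted p = 0.29 with an estimated correlation).

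For 50 genes of oxidative phosphorylation the median shift was -0.21, with mutant array medians of -0.17, -0.21 and -0.25 (camera adjusted p = 3.9e-07, but adjusted p = 0.29 with an estimated correlation), and no gene passed; cyc-2.2 differed by 0.94 (0.56 without ifo-1(kc2) replicate 3) and ucr-11 by -0.61 (-0.16 without ifo-1(kc2) replicate 1). For 30 genes of glycolysis, gluconeogenesis and glycogen it was -0.22 (camera adjusted p = 0.00257, but adjusted p = 0.384 with an estimated correlation), with 1 gene lower, the phosphoenolpyruvate carboxykinase gene pck-2 (-1.04), and 2 adjusted over the list alone (3 with arrays centred); pck-2 missed the threshold in all 6 fits with 1 array left out (adjusted p up to 0.141) and the list call was lost without ifo-1(kc2) replicate 1 (0.0598). The median was -0.14 without ifo-1(kc2) replicate 3. The 5 measured vitellogenin genes, for yolk proteins, had a median of -0.45 with none past the threshold, including -0.58 for vit-4 and -0.52 for vit-1 (camera adjusted p = 0.00257, but adjusted p = 0.443 with an estimated correlation). For 75 ribosomal protein genes the median was -0.08 (camera adjusted p = 0.000462, but adjusted p = 0.443 with an estimated correlation), and the call was lost after a second quantile normalization (0.268). Of these genes rps-15A differed by -0.39 and rpl-37.1 by -0.38 (-0.46 to -0.24 with 1 array left out). The oxidative phosphorylation, ribosomal and vitellogenin lists had N2 median levels of 10.90, 12.75 and 12.91, against a median of 4.525 over all genes. PMK-1 effectors and muscle markers, which shifted up, lay at 9.11 and 9.23. Random lists of genes with like levels were not drawn for the lists of metabolism, so a shift tied to signal level was not tested there. The 18 genes of the mitochondrial unfolded protein response had a median of -0.14 (camera adjusted p = 0.0403, but adjusted p = 0.692 with an estimated correlation), with -0.50 for hsp-6 and -0.49 for spg-7, neither past the threshold; this call was lost under the second quantile normalization (0.106) and without N2 replicate 1 or ifo-1(kc2) replicate 3 (medians -0.08 and -0.07). In peroxisomal beta-oxidation 1 of 21 genes rose, ech-9 (2.68, SE 0.35; adjusted p = 0.0569 without N2 replicate 3), and the list did not shift (median -0.05, adjusted p = 0.136; 0.0317 without ifo-1(kc2) replicate 2).

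Detoxification genes changed in both directions. Of 67 UDP-glucuronosyltransferase genes, ugt-18 rose while ugt-31, ugt-32 and ugt-26 fell by 1.71, 1.96 and 1.88 on the log2 scale (5 higher and 10 lower adjusted over the list alone); the median was -0.19, or -0.31 without ifo-1(kc2) replicate 1 (camera adjusted p = 0.0008, but adjusted p = 0.52 with an estimated correlation). With 1 array left out ugt-18 passed in all 6 fits and none of the 3 falls did (adjusted p up to 0.141). Under each of the other scalings 5 genes of the list were lower. Among 48 glutathione S-transferase genes, gst-4 fell from 10.03 ± 0.26 to 7.38 ± 0.36 (SD, n = 3), 6.32-fold, gst-10 fell by 1.92 and gst-22 rose by 1.28, and the same 3 passed adjusted over the list alone. That list did not shift (median -0.08, adjusted p = 0.155; 0.026 without N2 replicate 1). With 1 array left out only gst-4 passed in all 6 fits. The 35 genes of oxidative stress and phase II detoxification, with gst-4 and gst-10 as the 2 that fell, had a median of -0.10 (camera adjusted p = 0.0255, but adjusted p = 0.443 with an estimated correlation); the call was lost after a second quantile normalization (0.0667) and without N2 replicate 2 or ifo-1(kc2) replicate 1. Of 74 cytochrome P450 genes, cyp-13A5 and cyp-36A1 rose by 2.85 and 2.28 and cyp-25A1 fell by 2.67 (3 higher and 2 lower adjusted over the list alone), with no shift of the list (adjusted p = 0.976). Without N2 replicate 3, cyp-36A1 missed the threshold (0.056). The list of DAF-16 targets had 1 of 26 higher, the long non-coding RNA tts-1 (1.59, SE 0.31), or 2 higher and 3 lower adjusted over the list alone. With 1 array left out tts-1 passed in none of the 6 fits (adjusted p up to 0.149). The list had a median of -0.18 and a camera adjusted p of 0.028 (0.52 with an estimated correlation). Its call was lost under both other scalings (0.0935 and 0.0755) and without N2 replicate 1, where the median was 0.01, or ifo-1(kc2) replicate 1. The 20 genes of the metal response had a median of -0.42 with no gene past the threshold (camera adjusted p = 0.00414, but adjusted p = 0.377 with an estimated correlation); ftn-1 differed by -1.15 and hmt-1 by -0.93. The median was -0.26 and -0.28 without N2 replicate 2 and 3.

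Stress and regulatory lists showed few changes. Among 271 nuclear hormone receptor genes, nhr-63, nhr-112 and nhr-6 rose by 1.93, 2.38 and 2.19 and nhr-76 had a log2 change of -1.53; only nhr-63 passed in all 6 fits with 1 array left out, and the list did not shift (adjusted p = 0.672). No gene passed among 22 of the heat shock response. There hsp-16.2 differed by -2.58 with a standard error of 0.86 and hsp-12.3 by -2.37 with one of 1.07. The list median was -0.17 (camera adjusted p = 0.085), or -0.08 and -0.09 without ifo-1(kc2) replicate 2 and N2 replicate 1. The camera adjusted p was 0.0153 without N2 replicate 3, 0.00804 without ifo-1(kc2) replicate 3 and 0.478 without ifo-1(kc2) replicate 1. One gene rose in each of 2 lists that did not shift: osm-11 among 26 osmotic stress genes (1.09; 4 higher adjusted over the list alone; list adjusted p = 0.381) and F22B5.4 among 13 genes of the hypoxia and hydrogen sulfide response (2.80; list adjusted p = 0.381, with a median below 0 and a mean above). With 1 array left out osm-11 passed in none of the 6 fits and F22B5.4 in 1 (adjusted p up to 0.154 and 0.114). The endoplasmic reticulum unfolded protein response (26 genes; fkb-3 1.01, sel-11 -1.01) and the proteasome (33 genes; rpn-6.1 -0.33, pbs-2 -0.28) had no gene past the threshold and no shift (adjusted p = 0.976 and 0.478). Without ifo-1(kc2) replicate 1 the differences of sel-11 and rpn-6.1 were -0.06 and -0.04, without replicate 2 that of fkb-3 was 0.47, and without N2 replicate 1 that of hsp-12.3 was -0.95.

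At the apical surface of the intestinal cell, 2 structural genes with high signals rose. The actin-bundling plastin gene plst-1 went from 9.55 ± 0.22 to 12.57 ± 0.11 (SD, n = 3), 8.11-fold, at an adjusted p of 0.000818, and passed in all 6 fits with 1 array left out. The claudin gene clc-1 went from 11.03 ± 0.17 to 12.35 ± 0.02 (SD, n = 3), a log2 change of 1.32 (adjusted p = 0.0137); its call was lost without N2 replicate 1, N2 replicate 3 or ifo-1(kc2) replicate 2 (adjusted p up to 0.0681). plst-1 was the only one of 14 brush border and terminal web genes to pass, over all genes and adjusted over the list alone. Their median shift of 0.20 turned to -0.01 when arrays were centred, where the camera call (adjusted p = 0.0317, but adjusted p = 0.544 with an estimated correlation) was lost at 0.0755; it was also lost without N2 replicate 1 and ifo-1(kc2) replicates 2 and 3. The median was 0.33 and 0.12 without ifo-1(kc2) replicate 1 and 2. clc-1 was the only one of 24 apical junction and polarity genes to pass; the list had a median of 0.28 (camera adjusted p = 0.00957, but adjusted p = 0.55 with an estimated correlation) and lost its call without ifo-1(kc2) replicate 2. Lists of intestinal function changed in few genes. Among 37 digestive and lysosomal proteases, cpr-3 and asp-12 rose by 1.72 and 1.52 and asp-14 had a log2 change of -1.05 (0 higher and 3 lower with arrays centred; 2 higher and 2 lower adjusted over the list alone; none of the 3 in all 6 fits with 1 array left out; list adjusted p = 0.133). In the defecation motor programme, 1 of 24 genes rose, gem-4 (1.89), and the list did not shift (list adjusted p = 0.928). With 1 array left out gem-4 passed in 1 of the 6 fits (adjusted p up to 0.16). No gene passed among 19 of the V-ATPase (vha-16 -0.82, vha-5 0.61), 33 of endocytosis and membrane traffic (alx-1 0.66, ehbp-1 -0.55), 34 of gut granules and autophagy (apd-3 -0.89, lgg-2 0.84) and 32 of nutrient and ion transport (hrg-1 1.42; aat-2 5.06 in N2 and 6.15 in the mutant), and these lists did not shift (adjusted p = 0.315, 0.36, 0.709 and 0.553). Without ifo-1(kc2) replicate 1 the difference of vha-16 was -0.07.

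Markers of tissues other than the intestine lay higher in the mutant pools for some tissues and not for others. All 21 body wall muscle markers had a higher mean in ifo-1(kc2), with a median shift of 0.45, array medians of 0.57, 0.49 and 0.48, and no gene past the threshold, or 1 adjusted over the list alone (pat-10 0.82, unc-27 0.75; camera adjusted p = 1.3e-06, but adjusted p = 0.443 with an estimated correlation). All 30 sperm markers had a higher mean, with a median of 0.70, array medians of 0.71, 0.40 and 1.34 (0.42 without ifo-1(kc2) replicate 3) and 2 genes higher, ssp-31 (1.64) and ssp-36 (1.25), or 6 adjusted over the list alone; neither passed in all 6 fits with 1 array left out (camera adjusted p = 5.3e-07, but adjusted p = 0.443 with an estimated correlation). Hypodermis and cuticle markers had a median of 0.86, with 2.05 in ifo-1(kc2) replicate 2 against 0.61 and 0.29 in replicates 1 and 3, and no gene past the threshold (col-17 3.40, SE 1.08, and sqt-3 3.38, SE 1.23; camera adjusted p = 0.000462, but adjusted p = 0.463 with an estimated correlation; lost without replicate 2). The 172 collagen genes, 2 of them higher (col-109 3.12 and col-48 3.61), had a median of 0.51 (camera adjusted p = 4.9e-07, but adjusted p = 0.463 with an estimated correlation). Without ifo-1(kc2) replicate 3, 14 collagen genes were higher, and without N2 replicates 1 and 2, none. Among 27 genes of moulting and apical extracellular matrix, 1 rose, mlt-8 (3.23). With 1 array left out mlt-8 passed in 1 of the 6 fits (adjusted p up to 0.142). The median of this list was 0.46 (camera adjusted p = 0.00957, but adjusted p = 0.55 with an estimated correlation), and its call was lost without ifo-1(kc2) replicate 2. Neuron markers had a median of 0.35 (25 genes, none past the threshold and 2 adjusted over the list alone, flp-9 1.33, rab-3 0.83; camera adjusted p = 0.00237, but adjusted p = 0.443 with an estimated correlation; lost without ifo-1(kc2) replicate 3). Of 16 somatic gonad and vulva markers, zmp-1 rose by 2.28, in all 6 fits with 1 array left out (3 higher adjusted over the list alone), and the median of 0.35 had a camera adjusted p of 0.0327 (adjusted p = 0.41 with an estimated correlation; lost after a second quantile normalization, at 0.106, and without N2 replicate 3 or ifo-1(kc2) replicates 2 and 3).

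Markers of pharynx (median -0.15, 22 genes, phg-1 1.52 with SE 0.80, pqn-13 1.37 with SE 1.01), germline (0.00, 28 genes, htp-1 0.44, egg-2 0.44), coelomocytes (-0.08, 5 genes, lgc-26 0.67, unc-122 0.43) and the excretory system and rectum (-0.05, 15 genes, exc-4 1.26, which rose, with adjusted p up to 0.151 with 1 array left out) did not shift, at camera adjusted p of 0.226, 0.478, 0.976 and 0.927. With 1 array left out the differences of phg-1, pqn-13, htp-1 and egg-2 fell as low as 0.62, 0.76, -0.06 and 0.13, and exc-4 passed in 1 of the 6 fits. Without N2 replicate 3 the germline list was called lower (adjusted p = 0.0187). The 19 intestine markers had a median of -0.01, 0.01 and -0.21 under the deposited scaling, the second quantile normalization and centring, with gem-4 as the 1 gene that rose and no shift of the list (adjusted p = 0.233). In all, 24 of the 47 lists, 13 up and 11 down, were called by camera with its preset correlation, none with an estimated one (smallest adjusted p = 0.29) and 12 by the directional test of fry, which asks whether a list's genes move one way on balance. The mixed test of fry, for change in either direction, called 36. Of the 24, 13 were called without each of the 6 arrays in turn. Median, mean and test differed in sign for 9 lists, none of them among the 24. Centring moves every list median down by as much as the median of all genes, so medians above 0 shrink (apical junction to 0.08, neurons to 0.15, body wall muscle to 0.25) and those below 0 grow (oxidative phosphorylation to -0.41).

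**Figure D3:**
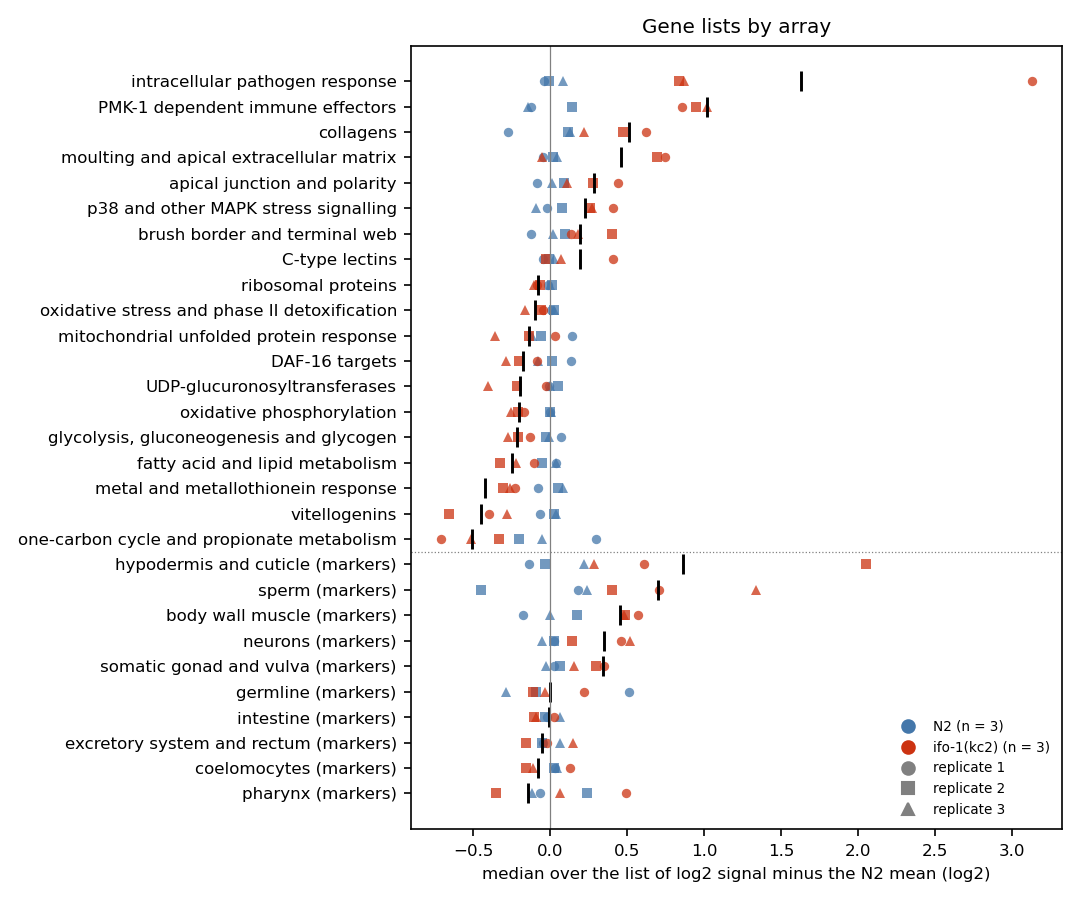
Median over each gene list of the log2 signal minus the N2 mean (horizontal axis, log2) for single arrays, with shapes for replicates and black ticks for the median log2 change of the list. Above the dotted line stand the lists other than tissue markers that camera called with its preset correlation. Below it stand all 10 lists of tissue markers, whether called or not. Mutant arrays lie at 0.83 to 3.13 for the intracellular pathogen response and at -0.10 to 0.02 for the intestine markers.

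Some probe sets are listed for several genes that they cannot separate, so these genes are not named. In the fit of all 28387 probe sets, 2 that share their listed genes rose from 6.01 ± 0.81 to 12.66 ± 0.24 and from 3.33 ± 0.35 to 9.80 ± 0.24 (SD, n = 3), 100.4-fold and 88.6-fold, more than any gene measured alone. Of those that fell, the largest change went from 12.45 ± 0.43 to 9.62 ± 0.47 (SD, n = 3), 7.15-fold, with the same values on 2 probe sets. These probe sets were chosen after their values were seen and lie outside the counts above.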

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

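Apart from the count over other splits of the arrays, the tests and the genes named in this part were chosen after the results were seen.

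Probe sets outside the gene-level comparison held signals that differed between the strains. Among 646 probe sets with several genes, 9 passed the adjusted threshold in the fit of all probe sets (4 higher and 5 lower, with 109 at an unadjusted p under 0.05). Among 2195 probe sets with no listed gene, 11 passed (4 higher and 7 lower, with 195 at an unadjusted p under 0.05).

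Markers of body wall, neurons and sperm lay higher in the mutant pools, though none of these lists was called with an estimated correlation (adjusted p 0.443 to 0.463). The median shift of muscle markers was 0.45, at percentile 99.98 of 10000 random lists matched on level, and those of cuticle, neuron and sperm markers lay at percentiles 100, 99.6 and 100, but random lists ignore the correlation between markers, 19 of 22 cuticle markers are in other lists, and the cuticle shift fell from 0.86 to 0.37 and lost its call without ifo-1(kc2) replicate 2. The raised low end of ifo-1(kc2) replicate 1 is argued against as the whole cause. Without that array the muscle shift was 0.53 (percentile 99.99), but muscle markers lie far above the low end (median N2 level 9.23). Cuticle, neuron and sperm markers lie at 4.66, 6.20 and 6.45. Their shifts without that array were 1.05, 0.29 and 0.80 (percentiles 100, 99.7 and 100). A smaller share of intestinal RNA would raise all other tissues alike only if each was carried along in the same proportion. Intestines were dissected without pharynx, so this need not hold for pharynx markers. Muscle exceeded the mean of germline and pharynx by 0.50, but the 95% interval over arrays ran from -0.16 to 1.15. For both reasons this explanation cannot be told apart with these markers and 3 arrays per strain. Body wall carried along with the intestine cannot be told apart from the other explanations. The 21 of 21 muscle markers that were higher are the pattern itself. Smaller mutant animals, pools of 80 against 40 and a real change in the strain stay open too. So does a difference of stage, which the marker lists were also fixed to see and which was not tested. Staining of dissected pools for muscle would test carry-over.

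Intracellular pathogen response genes lay higher, most in ifo-1(kc2) replicate 1, with 8 of 37 past the threshold and no call of the list with an estimated correlation (adjusted p = 0.433). The raised low end of that array is argued against as the whole cause: without it the median shift of the list was 0.77, where the central 95% of 10000 matched random lists, which ignore the correlation between members, ended at 0.14. Related pals probe sets reading a single transcript are argued against only as the whole cause. The 12 members outside the pals family had a median of 1.74 with that array and 0.77 without it (the central 95% of matched lists ended at 0.40 and 0.31). Whether pals probe sets read each other's transcripts was not tested. The larger shift of replicate 1 (3.13 against 0.83 and 0.87) rests on 1 array, and unequal exposure of the pools to a pathogen or stress, or a higher response in that isolate, may add to it and was not tested. A response of the mutant intestine is a hypothesis that reporters of pals genes in outcrossed mutants on sterile food would test.

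Some genes that fell lie next to each other. Without the chromosome end that prompted the test, 6 of 101 protein-coding genes that fell had another within 2 positions. The 10000 shuffles gave a median of 2 and an upper end of 6 for the central 95% (p = 0.0865, permutation test). Chance neighbours thus stay open for protein-coding genes, the only genes in this test. Genes that rose had a larger excess (123 of 405, shuffled median 33) that a lost stretch would not produce. The 2 largest falls, cgt-2 and cTel55X.1, are among the last 3 protein-coding genes tested on their chromosome. They kept 2.47% and 0.6% of the N2 signal and are the only genes there above the median level. Both prompted the look, so these low shares cannot serve as a test of the stretch. The gene between them, H11L12.1, differed by -0.84 from a low level and kept 55.93%. vab-8 (log2 change -2.40, limma adjusted p = 0.00953) and 6 of 17 ZK836 genes around it, each non-coding, fell in another stretch. In that stretch 16 of 18 genes had a negative difference. Its non-coding genes were outside the neighbour test, and the stretch was not tested on its own. None of the 20 nearest neighbours of ifo-1 passed. A sequence change in strain BJ142 besides ifo-1(kc2) may cause such losses, but cannot be told apart from silencing, since the arrays read only RNA and strain and allele coincide; sequencing the DNA of BJ142 would test it.

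Counts were also made for the 10 splits of the 6 arrays into 3 and 3. These are too few for a share under 0.05. Each of the others mixes the strains, so the strain difference enters its error and a low gene count was set in advance. Its list count still holds part of the strain difference. Neither count is therefore a measure of chance. The real split gave 552 changed genes, 535 at least 2-fold and 24 lists, and the highest of the other splits gave 0, 0 and 17; 1 split reached the real value in each case.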

How the results depend on the processing

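The alternatives were planned except the fit of protein-coding genes only. The count of 552 changed genes lay between 531 and 809 under the other scalings, filters, variance models with moderation, array weights, probe set rules and the protein-coding genes (594), and the count at least 2-fold between 501 and 713. It was 19 (17 at least 2-fold) without moderation of variances, which has 4 residual degrees of freedom per gene, and 1091 for both with an unadjusted p, a 2-fold change and no moderation. With 1 array left out both counts ranged from 161 to 407; fewer arrays give larger errors. With the replicate number as a block both were 327. The residuals showed no clear pairing by number. Those of arrays with the same number correlated at -0.02, 0.08 and -0.09, and only N2 replicate 2 among the N2 arrays correlated best with its own number. Residuals of the 3 arrays of a strain sum to 0 for each gene, so these correlations are tied to each other. What the numbers mark is not given in the sources used here, so pairing is not excluded. The 24 list calls were between 20 and 25 except with an estimated correlation (0), which asks the same question with a correlation estimated for each list, and with fry (12), which asks another, and ranged from 20 to 25 with 1 array left out. The ifo-1 change ranged from -2.22 to -1.77 (adjusted p 0.00294 to 0.139). It lost its call without moderation (-2.01, adjusted p = 0.139) and, with 1 array left out (-2.21 to -1.77), without N2 replicate 3 (adjusted p = 0.0548). No list was called in the opposite direction. Among the 24 called lists, 3 medians changed sign under another scaling or with 1 array left out: C-type lectins and brush border (both -0.01 with arrays centred) and DAF-16 targets (0.01 without N2 replicate 1). Of 78 named genes past the threshold, 70 to 78 of those fitted passed with the same sign under most settings, 59 with the block, 42 to 58 with 1 array left out and 5 without moderation. Signal over background was not measured, so falls to low signals such as cgt-2 (2.78) and rises from them such as Y26D4A.3 (2.77) are bounded only by the low end of the array.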

Other observations

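The tests, gene families and probe sets in this part were chosen after the data were seen. Grouping genes by the family part of their symbols (10 or more members) and testing each direction with Fisher's exact test singled out 4 families among the genes that rose. F-box genes of the fbxa family had 21 of 188 genes higher where 3.13 would be by chance (adjusted p = 2.6e-09), led by fbxa-30 (3.75), fbxa-158 (3.62) and fbxa-12 (3.31). Claudin-like clc genes had 10 of 30 higher where 0.50 would be by chance (adjusted p = 5.7e-09): clc-11, clc-32 (4.30), clc-13 (3.72) and clc-21 (3.24) rose most, while clc-15 (1.64), clc-23 (1.33) and clc-1 (1.32) rose from signals of 8.97, 8.19 and 11.03. The pals family had 6 of 37 and the C-type lectins 14 of 247 higher (adjusted p = 0.00358 and 0.00649). Without ifo-1(kc2) replicate 1 the counts were 16, 8, 7 and 13. Among genes that fell, carboxylesterase genes had 3 of 34 (adjusted p = 0.0462), cest-28, cest-10 (-1.86) and cest-2.1 (-1.57), but 1 without that array; cest-26 (1.55) and cest-35.1 (0.98) rose. Members of a family lie close together and share sequence, so they are not independent genes in this test.

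Genes that rose lay next to each other. Of 405 protein-coding genes that rose, 123 had another within 2 positions, against a median of 33 and an upper end of 50 for the central 95% of 10000 shuffles of the calls (p = 1e-04, permutation test, the smallest these shuffles can give). Tandem families were not removed from this count.

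Probe sets listed for several genes held values for families that the lists could not count. All 30 that list major sperm protein genes had a higher mean in ifo-1(kc2), with a median log2 difference of 0.78. None passed the threshold in limma (lowest adjusted p = 0.118). Many of the 30 list the same genes and some hold identical values, so they are not 30 separate measurements. All 4 that list small heat shock genes of the hsp-16 family had a lower mean, with a median of -2.42 and limma adjusted p between 0.173 and 0.205. Some of these share genes and identical values, so they are not 4 separate measurements.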
